A study of Homo sapiens with 4 samples.

How the data were processed

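Messenger levels of bone marrow mesenchymal stem cell cultures were read by RNA sequencing at the end of 21 days in osteoconductive medium, in 2 control and 2 nSi libraries. Per the labels' protocols, cells were seeded at 2500 per cm2, grown to 65% confluency and, in the nSi group, exposed to the particles, and total RNA was made into libraries by a standard Illumina protocol. Per the submitters' processing notes, the authors used bcl2fastq and STAR with genome build hg38. Versions, the counting tool and the gene annotation are not given in the sources used here. The authors deposited 1 table of RPKM (reads per kilobase of gene, scaled to the reads of the library), with a row per Entrez gene and a column per library, and every column matched a sample by its name.

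The table held 19479 genes, 4183 of them at 0 in every library. Symbols of 27 genes had turned into dates and were restored from their Entrez identifiers, and 47 rows of Y-linked and X-inactivation genes were left out. Mitochondrially encoded genes were not in the rows analysed here. The RPKM steps of low genes showed that whole reads had been counted: whole reads were recovered, within 0.002 reads, for 15293 of 15296 genes above 0 (99.98%), with the library totals given in the results. In 3000 simulated genes, each with its true length as the only candidate, all reads were recovered, which does not test the choice of length. Recovered reads of the listed genes summed to 100.4% to 100.7% of the recovered totals. Of the recovered gene lengths, 68.7% equal a coding length in the GENCODE annotation of the same build and 83.5% are multiples of 3. The recovery set the totals by agreement with GENCODE coding lengths and took such a length wherever one gave whole reads. Part of this agreement is therefore built in. RPKM appears to be per kilobase of coding length for most genes, not for all. For 264 of 15188 genes, RPS9, FLOT1 and IRF7 among them, the length was over 2 times the longest coding length. Their RPKM understates the level, while ratios between libraries do not depend on the length. The largest library total was 1.08 times the smallest. Replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 95.3 for the controls and 45.2 for nSi, and each counts as a separate sample. Intervals and 3-read limits cover counting error only. Coordinates and transcript GC content and length come from GENCODE on hg38 and were available for 11789 of the tested genes (99.6%).

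Genes with a mean of at least 0.5 RPKM over the 4 libraries were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a variance trend, no replicate block), 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Gene lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists with members above the filter out of 36 written. Camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction, were alternatives. After seeing the data the estimated correlation was also run on the scaled and GC-corrected values. Tests, lists, named genes and most alternatives were fixed before the data were examined. Named genes are the 12 largest rises and 12 largest falls among genes past the threshold whose nSi libraries both lay on one side of both controls, leaving out unnamed and non-coding symbols (LOC, LINC, MIR and similar prefixes) and the genes left out above. To these come up to 4 members of each described list with the smallest p, and a panel of 13 cartilage and bone genes reported whatever their values. Other genes are named to complete a count of 5 or fewer, or as members of lists in the closing section, and were chosen after their values were seen.

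Other settings fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 RPKM, median-ratio scaling, quantile normalization, other variance priors, the replicate number as a block, each library left out in turn, a 2-fold minimum and a threshold of 0.1. Added after seeing the data were a correction that smooths each library's deviation from the gene mean on transcript GC content and log2 length (generalized additive model, mgcv 1.9.3) and takes it off, the same with the GC smooth depending on level, the first with the replicate block, and limma's voom on the recovered reads. Recovery and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

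The gene test was tested on simulated data for nSi against control over 11788 genes, 200 of them changed. Reads were drawn from the real means and totals, with the real replicate spread shuffled over genes. Without a GC trend the test recovered 0 of 67 genes changed 2-fold, 2 of 67 changed 4-fold and 31 of 66 changed 8-fold, and called 0 of 11588 unchanged genes. With a GC trend close to that between the groups it recovered 24 of 67, 43 of 67 and 62 of 66, but also called 2602 of the unchanged genes. After the GC and length correction it called 0 of the unchanged genes and recovered 0 of 67, 1 of 67 and 24 of 66. The data held far more calls, 5438, and the adjustment is stricter where few genes change. These shares are therefore not the power of the test in the data. A simulated list of 30 genes all 2-fold higher gave camera p = 3.75e-21 and p = 0.00856 with an estimated correlation. Both p are unadjusted, and a lone list at the second would not pass adjustment over 35 lists. With 2 libraries per group, a list that does not pass with an estimated correlation is therefore not shown to be unchanged.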

Results

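RNA was measured in 4 libraries from human bone marrow mesenchymal stem cells, the stromal progenitors that can form bone, cartilage and fat. For the 2 libraries of the nSi group, cells grown in a flat layer had been exposed to 50 µg/mL of Laponite XLG nanosilicates, disc-shaped synthetic clay particles, for 48 h before 21 days in osteoconductive medium. The cells of the 2 control libraries spent the same 21 days in that medium without the particles. The design text asks whether nanosilicates, a component of a bone-printing ink, push these cells into endochondral differentiation, the route to bone through cartilage. Library totals were 11803623 and 11503198 reads in controls 1 and 2 and 12466879 and 12473233 reads in nSi 1 and 2. At these totals 10758, 10679, 11803 and 11846 genes held at least 10 reads, in the same order. Levels below are means ± SD of the 2 libraries of a group (n = 2) in RPKM. Log2 fold changes, nSi minus control, are given ± standard error on the log2(RPKM + 1) scale, which understates the change of low genes. The labels do not say that replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which can be technical.

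After nanosilicates, messages for connective tissue growth factor (CTGF), lumican (LUM), the collagen IV chain COL4A1, the collagen hydroxylases P4HA1 and PLOD2 and the clathrin heavy chain CLTC were higher. Messages for complement C3, the C1q relative C1QTNF1 and 26 of 53 cytosolic ribosomal proteins were lower. Of 11831 genes tested, 4186 (35.4%) were higher and 1252 (10.6%) lower in nSi libraries (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 3814 and 916 differed at least 2-fold. Counts of rises and falls in the gene lists below, as deposited, stand against these shares of all tested genes. The median log2 fold change of all tested genes was 0.44 as deposited. Median-ratio scaling moved that median to 0.0036 and quantile normalization to -0.09. The share of calls that were higher went with it, from 77.0% as deposited to 52.6% (2978 higher and 2687 lower) and 49.1% (2387 and 2475). Median-ratio scaling lowers nSi values of all genes alike, so list counts under it shift toward falls. The direction also followed base composition: the median transcript GC content was 42.9% for genes that rose and 61.0% for those that fell. Across 11789 genes, which are not independent replicates, fold change and GC content had a Spearman rho of -0.69. Of 10 equal groups of genes by GC content, the lowest had 74.9% of its genes higher and 0% lower. The group highest in GC content had 1.78% higher and 40.3% lower. A step chosen after seeing the data smoothed GC content and transcript length out of each library. It left 1179 genes higher and 866 lower, and 1117 of the rises and 218 of the falls stayed past the threshold in the same direction. Of 136 genes called as deposited among those named by rule, 87 kept their call. Without nSi replicate 1 the calls were 1471 and 13. Without nSi replicate 2 limma called 0 genes, with 3927 at an unadjusted p under 0.05. An exact permutation test of single genes cannot go below p = 0.333 with 2 against 2 libraries.

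**Figure D1:**
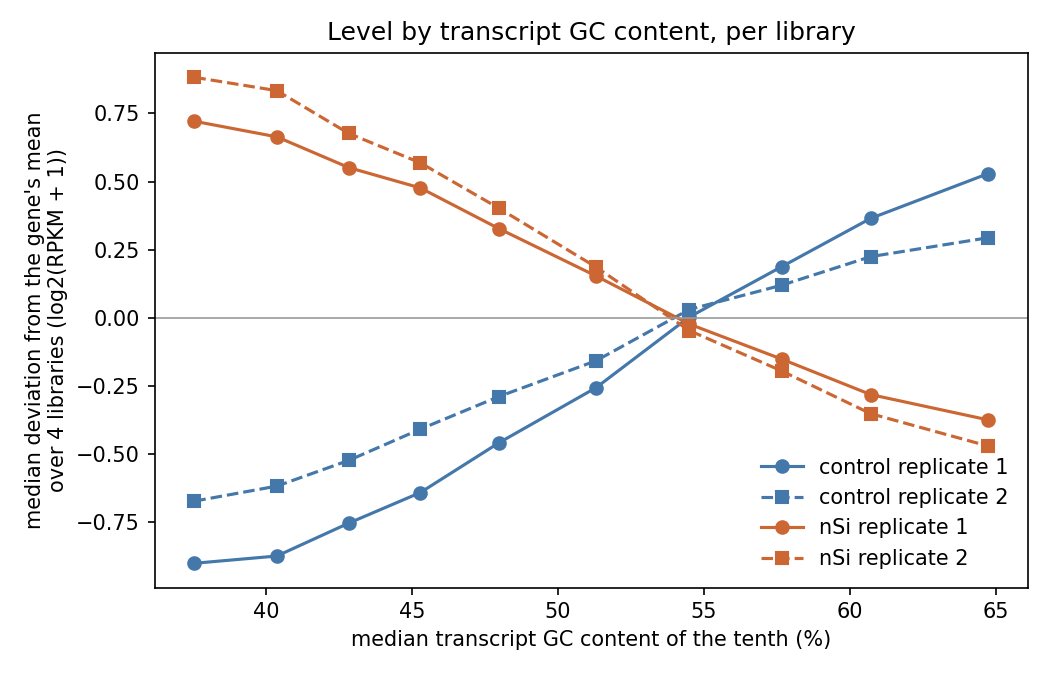
Median deviation of each library from the gene's mean over the 4 libraries (vertical axis, log2(RPKM + 1)) in 10 groups of genes of rising transcript GC content (horizontal axis, %), with 1 line per library. Both nSi lines run from 0.72 and 0.88 in the lowest group to -0.37 and -0.47 in the highest, and both control lines from -0.90 and -0.67 to 0.53 and 0.29.

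The largest rise was in a matrix gene. LUM (Entrez 4060, chromosome 12, 91102629 to 91111831, hg38), which encodes the collagen-binding proteoglycan lumican, rose from 3.98 ± 3.45 to 238 ± 48.9 RPKM (log2 fold change 5.77 ± 0.53, adjusted p = 0.00250). SERINC1, a membrane protein, rose from 1.96 ± 0.303 to 139.6 ± 51.5 RPKM (5.53 ± 0.34). The amino acid transporter gene SLC38A2 rose from 1.49 ± 1.05 to 107 ± 26.7 RPKM (5.48 ± 0.39), and PSAT1, an enzyme of serine synthesis, from 7.68 ± 3.02 to 282 ± 59.4 RPKM (5.06 ± 0.35). SEC23A, part of the coat of vesicles leaving the endoplasmic reticulum, rose from 0.654 ± 0.0911 to 53.1 ± 2.40 RPKM (5.03 ± 0.26). HIF1A, the hypoxia-regulated transcription factor, rose from 3.79 ± 0.772 to 163 ± 44.2 RPKM (5.08 ± 0.32), and TXNRD1, a thioredoxin reductase, from 5.79 ± 4.96 to 199 ± 25.4 RPKM (5.09 ± 0.55). The others among the 12 were C5orf15 (5.30), SRP9 (5.22), TCEA1 (5.19), NEK7 (5.18) and LMO7 (4.99), and the adjusted p was 0.00277 or less for each. All 12 had transcripts of low GC content, 35.7% to 43.8%, against a median of 49.7% over tested genes. After smoothing out GC content and length the 12 log2 fold changes were 3.25 to 4.04, and all 12 stayed past the threshold (largest adjusted p = 0.0223). Staying past it does not clear these rises of a library bias, since SEC23A, TCEA1 and HIF1A are genes that most cells use.

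The largest falls were led by C3 (Entrez 718, chromosome 19, 6677704 to 6730562), the central complement component, which fell from 57.2 ± 4.10 to 4.68 ± 3.68 RPKM (log2 fold change -3.53 ± 0.49, adjusted p = 0.00456). CXCL1, a chemokine that draws neutrophils, fell from 43.6 ± 19.1 to 6.81 ± 8.93 RPKM (-3.21 ± 1.02, adjusted p = 0.0466), and BDKRB1, a bradykinin receptor, from 134 ± 93.3 to 17.6 ± 14.0 RPKM (-2.91 ± 0.72). C1QTNF1, a secreted relative of complement C1q, fell from 51.8 ± 5.61 to 5.40 ± 4.02 RPKM (-3.20 ± 0.48), and CLU, the chaperone clusterin, from 53.7 ± 13.6 to 10.4 ± 3.73 RPKM (-2.28 ± 0.36). PCOLCE, which enhances the cleavage of procollagen, fell from 711 ± 378 to 146 ± 103 RPKM (-2.36 ± 0.61, adjusted p = 0.0260). The remaining falls were TMEM132A (-2.60), AKR1C1 (-2.40), PAMR1 (-2.33), ODF3B (-2.31), SMOC1 (-2.31) and POU2F2 (-2.27). AKR1C1 has close paralogs, so its level is uncertain where counting could split reads between them. After that smoothing 7 of the 12 stayed past the threshold. CXCL1 also lost its call without a filter (adjusted p = 0.109). Of the 5 that did not, CXCL1 (-3.87, adjusted p = 0.0553), BDKRB1 (-2.93, 0.0508) and SMOC1 (-2.08, 0.0801) kept most of their fold or more, and PCOLCE (-1.60, 0.101) and ODF3B (-1.21, 0.154) had smaller ones.

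The endochondral question was put to a list of cartilage and growth-plate genes. SOX9 (Entrez 6662, chromosome 17, 72121020 to 72126420), the master transcription factor of cartilage, rose from 1.04 ± 0.297 to 5.48 ± 1.67 RPKM (log2 fold change 1.65 ± 0.31, adjusted p = 0.00959). COL11A1, a minor fibrillar collagen of cartilage, rose from 0.129 ± 0.183 to 2.51 ± 0.194 RPKM (1.64 ± 0.26, adjusted p = 0.00603). FIBIN, a secreted protein of limb development, rose from 2.69 ± 0.905 to 18.7 ± 5.34 RPKM (2.41 ± 0.34), and HAPLN1, the link protein of aggrecan, from 19.8 ± 19.98 to 161 ± 102 RPKM (3.25 ± 0.85). MATN3, a cartilage matrilin, was listed at 0 in both controls, where 3 reads would be 0.174 and 0.179 RPKM. It was at 1.59 ± 1.01 RPKM in nSi libraries, at least 9.03-fold higher (adjusted p = 0.0240). SNORC, a chondrocyte membrane proteoglycan, fell from 2.43 ± 1.18 to 0.663 ± 0.104 RPKM (-1.003 ± 0.32, adjusted p = 0.0480). SNORC and HAPLN1 are named to complete the counts, after their values were seen. The genes that define mature cartilage showed no call. COL2A1 had 1 read in nSi 2 and none elsewhere, where 3 reads would be 0.0584 RPKM or less, so it was not detectable in the other 3 libraries at this depth. ACAN, the aggrecan gene, stood at 0.329 ± 0.465 RPKM in controls and 0.687 ± 0.702 in nSi libraries (0.32 ± 0.41, adjusted p = 0.538). COL10A1, the collagen of hypertrophic cartilage, lay under the filter, with RPKM values of 0.0415 and 0 in controls and 0.667 and 0.0785 in nSi libraries.

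COMP, a cartilage matrix protein, differed more between replicates than between groups, at 91.9 and 1.30 RPKM in controls 1 and 2 and 67.9 and 23.0 in nSi 1 and 2 (1.48 ± 1.65, adjusted p = 0.490). Of 37 cartilage genes in the file 13 were tested, of which 5 rose, 1 fell and 7 did not pass (5 and 1 adjusted over the list alone), against 4 higher and 1 lower under median-ratio scaling. Their median log2 fold change was 1.32, or 1.14 with MATN3 at its bound, against 0.44 for all genes. As a list they did not stand apart from other genes (camera, adjusted p = 0.629). Their share of rises, 5 of 13, was near the 35.4% of all tested genes. After smoothing out GC content and length only FIBIN remained past the threshold (1.94, adjusted p = 0.0280). SOX9 was at 0.94 (adjusted p = 0.0654), COL11A1 at 0.65 (0.153), MATN3 at 0.18 (0.714), HAPLN1 at 1.47 (0.310) and SNORC, its sign changed, at 0.08 (0.836). The smooth does not depend on level, so corrected values of genes near 0 in controls, MATN3 and COL11A1 among them, are uncertain. The SOX9 call also ended under quantile normalization (adjusted p = 0.0886).

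Genes of bone formation moved in both directions. TNFRSF11B, which encodes osteoprotegerin, the decoy receptor that restrains osteoclasts, rose from 18.2 ± 6.41 to 398 ± 115 RPKM (log2 fold change 4.39 ± 0.36, adjusted p = 0.00249). SPARC, the matrix glycoprotein osteonectin, rose from 1582 ± 0.208 to 6538 ± 34.3 RPKM (2.05 ± 0.21), and the transcription factor gene CBFB (1.99 ± 0.30) rose from a low level. COL1A1 (Entrez 1277, chromosome 17, 50183289 to 50201632), the main collagen of bone, rose from 2882 ± 793 to 5369 ± 577 RPKM (0.92 ± 0.28, adjusted p = 0.0402). BGLAP (Entrez 632, chromosome 1, 156241962 to 156243321), the late osteoblast gene osteocalcin, fell from 28.04 ± 15.3 to 8.87 ± 0.933 RPKM (-1.45 ± 0.42, adjusted p = 0.0359). CLEC11A, an osteogenic growth factor named to complete the count, fell from 324 ± 49.7 to 123 ± 2.26 RPKM (-1.38 ± 0.26). Of the other early and late markers, RUNX2 stood at 0.860 ± 0.828 RPKM in controls and 1.24 ± 0.466 in nSi libraries (0.33 ± 0.39, adjusted p = 0.510) and ALPL at 27.3 ± 13.7 RPKM in controls and 21.6 ± 4.46 in nSi libraries (-0.24 ± 0.41, 0.650). SPP1 stood at 2.58 ± 3.31 RPKM in controls and 4.17 ± 3.58 in nSi libraries (0.74 ± 0.84, 0.4996) and IBSP at 0.977 ± 1.38 RPKM in controls and 1.43 ± 1.90 in nSi libraries (0.24 ± 0.74, 0.810). SP7, the osterix gene, was listed at 0 in all 4 libraries, where 3 reads would be 0.186 to 0.201 RPKM. Across the 22 members tested, 9 rose, 2 fell and 11 did not pass, against 6 higher and 2 lower under median-ratio scaling (10 and 2 adjusted over the list alone). Their median log2 fold change was 0.90, and the list did not stand apart from other genes (camera, adjusted p = 0.629). After smoothing 4 were higher, namely TNFRSF11B (3.08), DLX5 (1.85), COL1A1 (1.26) and SPARC (0.93), DLX5 being named to complete the count. BGLAP was then at -0.44 (adjusted p = 0.443). The COL1A1 call also ended under median-ratio scaling (log2 fold change 0.35, adjusted p = 0.370) and with each library left out.

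**Figure D2:**
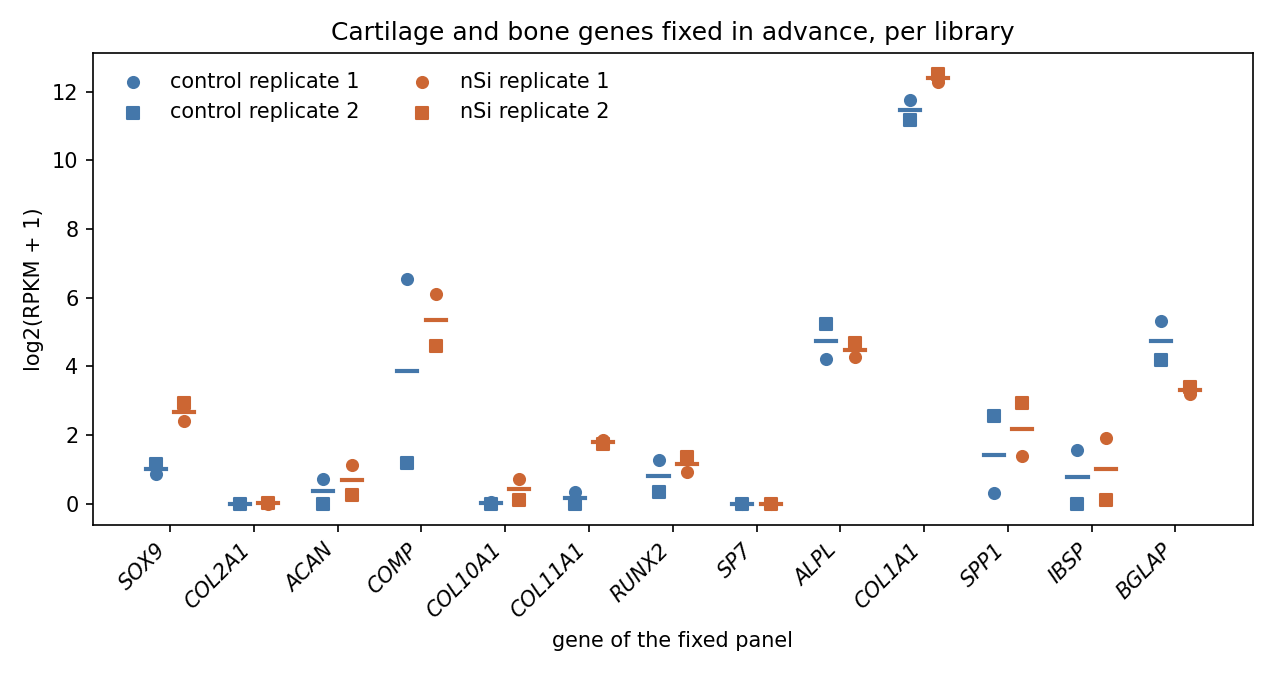
Level of the 13 cartilage and bone genes fixed in advance, as log2(RPKM + 1) on the vertical axis, with 1 point per library (circles replicate 1, squares replicate 2) and a bar at each group mean. SOX9 and COL11A1 are higher and BGLAP lower in both nSi libraries than in both controls, while COMP spans 1.30 to 91.9 RPKM within the controls.

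Several matrix collagens rose. COL4A1, a basement membrane collagen, rose from 31.2 ± 9.85 to 272 ± 79.5 RPKM (log2 fold change 3.08 ± 0.35, adjusted p = 0.00313). COL5A2, which regulates fibril diameter, rose from 32.2 ± 0.101 to 160.5 ± 54.3 RPKM (2.24 ± 0.32), COL12A1 from 3.58 ± 2.96 to 31.2 ± 3.69 RPKM (2.98 ± 0.50) and COL6A3 from 53.8 ± 1.47 to 211 ± 76.0 RPKM (1.90 ± 0.33). In the collagen list 9 of 20 members rose and 2 fell, against 5 higher and 3 lower under median-ratio scaling (9 and 2 adjusted over the list alone). The falls, named to complete the count, were COL6A2 (-1.57) and COL18A1 (-1.06). After smoothing the count was 8 higher and 0 lower. The list then stood above other genes (camera, adjusted p = 0.00447; adjusted p = 0.747 with an estimated correlation), which it did not as deposited (adjusted p = 0.625). Enzymes that modify and crosslink collagen gave 6 rises and 1 fall among 22, against 4 higher and 8 lower under median-ratio scaling and 5 higher and 1 lower under quantile normalization (5 and 1 adjusted over the list alone; camera, adjusted p = 0.789). The hydroxylase gene P4HA1 rose from 9.75 ± 0.945 to 156 ± 76.2 RPKM (3.78 ± 0.40) and PLOD2 from 12.7 ± 5.24 to 336 ± 227 RPKM (4.48 ± 0.56). The crosslinking oxidase LOX rose from 119 ± 35.6 to 743 ± 182 RPKM (2.64 ± 0.33) and PCOLCE2 by 2.03, and PCOLCE was the fall. Smoothing gave 4 higher and 0 lower, and LOX was then at 0.90 (adjusted p = 0.120).

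Other matrix genes moved too. Among proteoglycans and glycoproteins 11 of 30 rose and 2 fell, against 9 higher and 4 lower under median-ratio scaling (11 and 2 adjusted over the list alone; camera, adjusted p = 0.629). Besides LUM and SPARC, FBN1, the microfibril protein fibrillin, rose from 11.8 ± 1.61 to 167 ± 70.5 RPKM (log2 fold change 3.66 ± 0.37) and NID1, a basement membrane linker, from 1.43 ± 0.412 to 8.44 ± 1.87 RPKM (1.95 ± 0.30). The falls, named after their values were seen, were MFAP2 (-0.96) and LAMA4 (-1.43). Glycosaminoglycan synthesis gave 12 rises and 2 falls among 30, against 8 higher and 6 lower under median-ratio scaling and 8 higher and 5 lower under quantile normalization (12 and 2 adjusted over the list alone; camera, adjusted p = 0.789). UGDH, which makes the glucuronic acid donor, rose from 5.07 ± 1.93 to 57.7 ± 1.97 RPKM (3.31 ± 0.32), and the sulfate-donor synthase PAPSS1 from 6.83 ± 1.68 to 72.8 ± 21.7 RPKM (3.22 ± 0.34). The dermatan sulfate epimerase DSE rose from 2.45 ± 0.438 to 28.2 ± 3.29 RPKM (3.09 ± 0.28) and CHSY3 from 0.0976 ± 0.0476 to 4.71 ± 0.790 RPKM (2.37 ± 0.26), while HAS3 (-0.81) and B3GAT3 (-1.39) fell. Of 17 matrix proteases and inhibitors 3 rose and 0 fell, against 3 higher and 0 lower under median-ratio scaling (3 and 0 adjusted over the list alone; camera, adjusted p = 0.919). ADAMTS1, an aggrecan-cleaving protease, rose from 11.5 ± 0.961 to 156 ± 38.0 RPKM (3.64 ± 0.29), TIMP3, an inhibitor of metalloproteases, from 71.8 ± 19.8 to 396 ± 90.6 RPKM (2.45 ± 0.32), and ADAM12 from 8.25 ± 2.93 to 35.0 ± 10.3 RPKM (1.97 ± 0.36). ADAMTS4 was at 0.175 ± 0.0256 RPKM in controls and 0.979 ± 0.377 in nSi libraries (0.74 ± 0.26, adjusted p = 0.0611). Once GC content and length were smoothed out, these 3 lists gave 7 higher and 1 lower, 7 higher and 2 lower and 2 higher and 0 lower.

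Signalling lists contained some of the strongest changes. CTGF (Entrez 1490, chromosome 6, 131948176 to 131951373), a matricellular protein induced by TGF-beta, rose from 94.1 ± 15.8 to 2870.4 ± 431 RPKM (log2 fold change 4.92 ± 0.27, adjusted p = 0.00249), and stood at 4.52 with GC content and length smoothed out. In the TGF-beta list 13 of 20 members rose and 4 fell, against 9 higher and 4 lower under median-ratio scaling (13 and 4 adjusted over the list alone; camera, adjusted p = 0.398). The receptor gene TGFBR2 rose from 3.31 ± 1.19 to 39.1 ± 8.43 RPKM (3.23 ± 0.33), the repressor SKIL from 0.667 ± 0.106 to 17.1 ± 2.06 RPKM (3.44 ± 0.27), and the cell cycle inhibitor CDKN2B, from 4.20 ± 1.99 to 56.1 ± 1.23 RPKM (3.51 ± 0.35). The falls, named to complete the count, were IL11 (-1.92), LTBP3 (-1.26) and the ligands TGFB1 (-1.10) and TGFB3 (-0.96). Smoothing gave 7 higher and 2 lower and a list above other genes (camera, adjusted p = 0.0275; adjusted p = 0.747 with an estimated correlation). In the BMP list 6 of 19 rose and 0 fell, against 5 higher and 0 lower under median-ratio scaling (6 and 0 adjusted over the list alone; camera, adjusted p = 0.471). They included ID4, from 0.177 ± 0.00322 to 9.74 ± 2.80 RPKM (3.16 ± 0.30), the receptors BMPR1A (2.64 ± 0.31) and BMPR2 (1.66 ± 0.25), and SMAD1 (2.07 ± 0.24). Smoothing gave 3 higher and 1 lower and left BMPR2 at 0.14 (adjusted p = 0.709).

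WNT-related genes gave 5 rises among 10, against 4 higher and 0 lower under median-ratio scaling (6 and 0 adjusted over the list alone; camera, adjusted p = 0.471). The antagonist DKK1 rose from 54.9 ± 33.5 to 409.6 ± 115 RPKM (log2 fold change 2.99 ± 0.48) and CCND1, which encodes cyclin D1, from 54.6 ± 26.7 to 293 ± 71.2 RPKM (2.47 ± 0.41). The others were SFRP4 (3.31 ± 0.63), WNT5A (1.65 ± 0.31) and DKK3 (1.80 ± 0.58), the last named to complete the count. With GC content and length smoothed out CCND1 stayed past the threshold (1.66, adjusted p = 0.0387). DKK3 (2.55, 0.0511), SFRP4 (2.21, 0.0865), DKK1 (1.94, 0.0685) and WNT5A (0.14, 0.774) did not. Immediate early and feedback genes of the MAPK route gave 10 rises and 2 falls among 24, against 10 higher and 4 lower under median-ratio scaling (11 and 2 adjusted over the list alone; camera, adjusted p = 0.518). FOS rose from 5.63 ± 4.40 to 66.2 ± 26.0 RPKM (3.46 ± 0.55), and the phosphatase gene DUSP1 from 38.4 ± 14.1 to 187 ± 1.63 RPKM (2.30 ± 0.33). The feedback inhibitors SPRY2 (2.42 ± 0.32) and SPRED2 (1.83 ± 0.29) rose too, whereas DUSP4 (-1.35) and ETV4 (-1.76), named for completeness, fell. Smoothing gave 5 higher and 1 lower for this list (camera, adjusted p = 0.0198; adjusted p = 0.747 with an estimated correlation). In the hedgehog list limma called 0 of 6 members (camera, adjusted p = 0.789), and GLI2 (0.48 ± 0.25, adjusted p = 0.153), GAS1 (0.81 ± 0.64), SMO (-0.36 ± 0.36) and SUFU (0.23 ± 0.29) had the smallest p.

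The p53 list held more rises than falls, and few cell cycle genes passed. Of 23 p53 and growth-arrest genes 12 rose and 0 fell, against 11 higher and 4 lower under median-ratio scaling and 9 higher and 1 lower under quantile normalization (13 and 0 adjusted over the list alone; camera, adjusted p = 0.256). CDKN1B, the cyclin-dependent kinase inhibitor p27, rose from 0.859 ± 0.391 to 17.7 ± 1.04 RPKM (log2 fold change 3.34 ± 0.29) and GADD45A, a stress-induced arrest gene, from 31.4 ± 11.9 to 323 ± 21.6 RPKM (3.37 ± 0.33). The death receptor gene FAS rose from 3.49 ± 0.0636 to 51.6 ± 9.99 RPKM (3.54 ± 0.28) and SESN1 from 0.294 ± 0.0744 to 8.74 ± 1.25 RPKM (2.91 ± 0.26). After smoothing 11 were higher and 0 lower, and the list stood above other genes (camera, adjusted p = 1.82e-05; adjusted p = 0.747 with an estimated correlation). In the cell cycle list 4 of 31 rose and 1 fell, against 0 higher and 4 lower under median-ratio scaling and 1 higher and 8 lower under quantile normalization (0 and 0 adjusted over the list alone; camera, adjusted p = 0.189). PCNA (1.17 ± 0.26), MCM6 (1.13 ± 0.27), CCNA2 (1.22 ± 0.35) and CCNE1 (0.95 ± 0.29) rose, and AURKB (-1.78), named to complete the count, fell. Smoothing gave 0 higher and 5 lower and a list below other genes (camera, adjusted p = 0.00136; adjusted p = 0.747 with an estimated correlation). The members lower after smoothing were BUB1 (-1.63), BUB1B (-1.48), CDC6 (-1.31), CENPF (-1.42) and KIF11 (-1.50), named to complete the count. Replication-dependent histones gave 3 rises among 9, against 1 higher and 2 lower under quantile normalization (3 and 0 adjusted over the list alone; camera, adjusted p = 0.867). HIST1H2AC (2.09 ± 0.39), HIST1H2BC (1.72 ± 0.38) and HIST2H2BE (1.39 ± 0.33) rose, and HIST1H1E was at -0.65 ± 0.28 (adjusted p = 0.106). Smoothing gave 2 higher and 0 lower for the histones.

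Genes of particle uptake moved apart. The clathrin heavy chain gene CLTC rose from 6.41 ± 2.501 to 84.4 ± 15.3 RPKM (log2 fold change 3.56 ± 0.34, adjusted p = 0.00259), and its adaptor PICALM from 5.69 ± 1.94 to 82.2 ± 28.4 RPKM (3.63 ± 0.37). EPS15 rose from 0.354 ± 0.0282 to 8.42 ± 0.485 RPKM (2.80 ± 0.25) and the caveolin gene CAV1 from 19.8 ± 2.28 to 259 ± 52.9 RPKM (3.63 ± 0.28). In all 12 of 27 endocytosis genes rose and 5 fell, against 11 higher and 10 lower under median-ratio scaling (12 and 6 adjusted over the list alone; camera, adjusted p = 0.919). The falls were the dynamins DNM1 (-1.33) and DNM2 (-0.83), the flotillins FLOT1 (-1.23) and FLOT2 (-0.97), and EPN1 (-0.89), all named to complete the count. Smoothing gave 8 higher and 0 lower, with CLTC (2.17), PICALM (2.45), EPS15 (1.02) and CAV1 (2.29) among the rises. Lysosomal genes gave 8 rises and 2 falls among 33, against 4 higher and 12 lower under median-ratio scaling (6 and 2 adjusted over the list alone; camera, adjusted p = 0.480). ASAH1 (2.66 ± 0.27) and TPP1 (1.94 ± 0.34) rose, and MAN2B1 (-1.74 ± 0.27) and MCOLN1 (-0.99) fell. Smoothing gave 3 higher and 2 lower for the lysosome and 3 higher and 0 lower for the metal list below. TPP1 was then at 1.19 (adjusted p = 0.0741). In the metal list 7 of 14 rose and 1 fell, against 3 higher and 4 lower under quantile normalization (7 and 3 adjusted over the list alone; camera, adjusted p = 0.919). Higher were the magnesium-permeable channel TRPM7 (2.72 ± 0.30), the magnesium transporters MAGT1 (2.58 ± 0.38) and SLC41A1 (1.75 ± 0.27) and the zinc and manganese importer SLC39A14 (2.99 ± 0.41). With smoothing MAGT1 was at 0.90 (adjusted p = 0.102), while TRPM7 (1.25), SLC41A1 (1.23) and SLC39A14 (1.88) kept their calls. MT1M, named to complete the count, fell (-2.06), and it has near-identical paralogs, so its reads are uncertain.

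Stress and metabolic genes were mixed. In the oxidative stress list 8 of 27 rose and 5 fell, against 5 higher and 10 lower under median-ratio scaling (8 and 5 adjusted over the list alone; camera, adjusted p = 0.471). TXNRD1, NFE2L2, which encodes NRF2 (3.16 ± 0.30), GCLC (2.75 ± 0.36), which starts glutathione synthesis, and CAT (2.21 ± 0.39) rose. Among the falls were the glutathione peroxidases GPX1 (-1.35), GPX3 (-1.83) and GPX4 (-1.28), and OSGIN1 (-1.32), all named after their values were seen. For the unfolded protein response 9 of 26 rose and 0 fell, against 5 higher and 2 lower under median-ratio scaling and 10 higher and 0 lower under quantile normalization (9 and 0 adjusted over the list alone; camera, adjusted p = 0.471). The share of rises in this list as deposited, as in the cartilage, proteoglycan and cholesterol lists among others, is near the 35.4% of all tested genes. DNAJB9, a chaperone of the endoplasmic reticulum, rose from 1.86 ± 0.666 to 41.0 ± 11.8 RPKM (3.87 ± 0.34), with CANX, which encodes calnexin (3.89 ± 0.41), HERPUD1 (2.74 ± 0.29) and DNAJC3 (2.02 ± 0.30). Cholesterol synthesis gave 9 rises and 3 falls among 24, against 7 higher and 7 lower under median-ratio scaling (9 and 3 adjusted over the list alone; camera, adjusted p = 0.919). MSMO1 (3.96 ± 0.32), IDI1 (2.98 ± 0.27), HMGCS1 (2.71 ± 0.26) and SC5D (3.73 ± 0.45) rose, and EBP (-1.16), MVD (-1.11) and PMVK (-0.996) fell. In hypoxia and glycolysis 9 of 29 rose and 3 fell, against 6 higher and 8 lower under median-ratio scaling and 8 higher and 0 lower under quantile normalization (9 and 1 adjusted over the list alone; camera, adjusted p = 0.919). LDHA rose from 736 ± 31.8 to 2118 ± 665 RPKM (1.49 ± 0.29), with HK2 (1.97 ± 0.34), KDM3A (2.15 ± 0.34) and BNIP3 (1.62 ± 0.32), and ALDOA (-0.89), GPI (-0.86) and PKM (-0.76) fell. Smoothing gave 3 higher and 2 lower for oxidative stress and 3 higher and 0 lower for the unfolded protein response. It gave 6 higher and 1 lower for cholesterol synthesis and 3 higher and 1 lower for hypoxia and glycolysis. With smoothing LDHA (0.22), BNIP3 (0.39) and KDM3A (0.87) lost their calls (adjusted p = 0.109 or more), while HK2 kept its call (1.30, adjusted p = 0.0410). Of the falls in that list GPI (-1.35) kept its call, and ALDOA (-0.19) and PKM (-0.52) did not.

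Inflammatory genes split. Alongside the falls of C3 and CXCL1, the non-canonical NF-kB genes RELB (-1.40) and NFKB2 (-1.28), named to complete the count, fell. TNFAIP3, an inhibitor of NF-kB, rose from 3.25 ± 1.31 to 19.3 ± 2.86 RPKM (log2 fold change 2.29 ± 0.33). VCAM1, an adhesion molecule, rose from 3.34 ± 4.18 to 95.6 ± 71.4 RPKM (4.69 ± 0.89) and BIRC3 from 0.331 ± 0.00603 to 2.70 ± 0.751 RPKM (1.46 ± 0.27). In total 8 of 28 cytokine and NF-kB genes rose and 4 fell, against 4 higher and 7 lower under median-ratio scaling (8 and 4 adjusted over the list alone; camera, adjusted p = 0.625). Smoothing gave 2 higher and 5 lower, with CCL2 (-2.39), CXCL3 (-2.39) and CXCL6 (-2.35) joining C3 and NFKB2 among the falls. VCAM1 was then at 3.16 (adjusted p = 0.0852) and BIRC3, its sign changed, at -0.41 (0.360). Complement and acute-phase genes gave 3 rises and 3 falls among 15, against 1 higher and 4 lower under median-ratio scaling (3 and 3 adjusted over the list alone; camera, adjusted p = 0.471). The complement regulator CD46 (3.83 ± 0.37) and the acute-phase gene SAA1 (2.06), the latter named after its value was seen, were among the rises, and C3, C1QTNF1 and CLU were the falls. For type I interferon 7 of 27 rose and 4 fell, against 4 higher and 6 lower under median-ratio scaling (7 and 4 adjusted over the list alone; camera, adjusted p = 0.480). IFIT5 (2.28 ± 0.32) and SAMD9L (2.25 ± 0.35) rose, and IFI35 (-1.51 ± 0.28), IRF7 (-1.63), ISG15 (-1.46) and OAS1 (-1.80) fell. Smoothing gave 0 higher and 3 lower for interferon and 1 higher and 3 lower for complement. IFIT5 was then at 0.47 (adjusted p = 0.220), SAMD9L at 0.59 (0.182) and IFI35 at -0.84 (0.0651). SAA1 has a near-identical neighbour, so its reads are uncertain.

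Many messages of ribosomal proteins fell. RPS3, a protein of the small ribosomal subunit, fell from 4677 ± 484 to 1934 ± 181 RPKM (log2 fold change -1.27 ± 0.23, adjusted p = 0.00894). RPL18 fell from 3342 ± 53.6 to 1434 ± 134 RPKM (-1.22 ± 0.23), and RPS9 had a log2 fold change of -1.43 ± 0.26. Of 53 cytosolic ribosomal protein genes 26 fell and 0 rose (30 and 0 adjusted over the list alone), with a median log2 fold change of -0.74. The list stood below other genes by camera (adjusted p = 4.73e-14 with the preset correlation of 0.01; adjusted p = 0.970 with an estimated correlation). The fall held under each scaling, with 51 members lower under median-ratio scaling and 12 under quantile normalization and 0 higher in either. After smoothing out GC content and length 32 were lower. Ribosomal protein genes have many processed pseudogenes, so their reads are uncertain where counting could split them. In the list of nuclear oxidative phosphorylation genes 7 of 40 fell and 3 rose, against 22 lower and 2 higher under median-ratio scaling (6 and 2 adjusted over the list alone). The complex I genes NDUFS8, from 544 ± 77.1 to 176 ± 23.0 RPKM (-1.62 ± 0.26), and NDUFV1, from 239 ± 0.953 to 90.5 ± 5.68 RPKM (-1.39 ± 0.24), were among the falls. The rises were SDHD (1.72 ± 0.29), NDUFB5 (1.56 ± 0.28) and NDUFS1 (1.22), the last named to complete the count. Smoothing gave 0 higher and 13 lower, with SDHD at 0.61 (adjusted p = 0.146), NDUFB5 at 0.70 (0.126) and NDUFS1, its sign changed, at -0.40 (0.357). This list too stood below other genes (camera, adjusted p = 0.000874; adjusted p = 0.970 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.360) and without control replicate 2 (adjusted p = 0.0998). By fry neither list passed (adjusted p = 0.131 for ribosomal proteins and 0.368 for oxidative phosphorylation). These were the 2 lists of 35 past camera's threshold as deposited, the smallest adjusted p of the others being 0.189. Under quantile normalization 5 lists passed. Ribosomal proteins and the cell cycle stood below other genes, and p53 and the unfolded protein response above (adjusted p = 0.0295 for each), with the TGF-beta response (adjusted p = 0.0345). None passed there with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each).

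Markers of cell identity were read in the same way. Of 15 surface markers of mesenchymal stromal cells 7 rose and 1 fell, against 6 higher and 2 lower under median-ratio scaling (7 and 2 adjusted over the list alone; camera, adjusted p = 0.629). ALCAM rose from 0.875 ± 0.0528 to 31.8 ± 12.1 RPKM (log2 fold change 4.08 ± 0.34) and ITGB1 from 41.5 ± 28.6 to 789 ± 197 RPKM (4.38 ± 0.52). NT5E, which encodes CD73, rose from 38.5 ± 0.315 to 143 ± 17.4 RPKM (1.86 ± 0.26), and ANPEP, named to complete the count, fell (-1.23). Smoothing gave 3 higher and 1 lower, and NT5E was then at 0.33 (adjusted p = 0.342). In the contractile list 4 of 16 rose and 3 fell, against 3 higher and 5 lower under median-ratio scaling (3 and 3 adjusted over the list alone; camera, adjusted p = 0.480). CALD1 (3.97 ± 0.41), MYLK (2.89 ± 0.30), TPM1 (1.76 ± 0.27) and SYNPO2 (1.12) rose, and TGFB1I1 (-1.80 ± 0.31), MYL9 (-0.98) and CSRP1 (-1.29) fell. Of 16 adipocyte genes 3 rose and 1 fell, against 3 higher and 3 lower under median-ratio scaling (3 and 1 adjusted over the list alone; camera, adjusted p = 0.906). ACSL1 (2.22 ± 0.28), CD36 (2.47 ± 0.39) and ADIPOR2 (1.48 ± 0.28) rose and APOE fell (-1.04 ± 0.29). Smoothing gave 3 higher and 1 lower in the contractile list and 1 higher and 0 lower in the adipocyte list, and none of these 4 adipocyte genes kept its call. ACSL1 was then at 0.97 (adjusted p = 0.0775), CD36 at 1.03 (0.155) and ADIPOR2 at 0.35 (0.323), and in the contractile list SYNPO2, its sign changed, at -0.22 (0.731). In the tenocyte list EGR1 rose (2.12 ± 0.37), and MKX (0.77 ± 0.26, adjusted p = 0.0527), COL14A1 (0.88 ± 0.62) and TNC (-0.46 ± 0.42) did not pass (1 and 0 adjusted over the list alone of 7; camera, adjusted p = 0.919). Among 4 endothelial genes above the filter TEK rose from 1.37 ± 0.0469 to 10.7 ± 1.11 RPKM (2.29 ± 0.26), and PECAM1 fell from 1.39 ± 0.0254 to 0.307 ± 0.179 RPKM (-0.88 ± 0.25). ROBO4 (-0.20 ± 0.24) and ESAM (-0.23 ± 0.40) did not pass (1 and 1 adjusted over the list alone; camera, adjusted p = 0.649). Of 3 blood-cell genes CD68, which stromal cells also express, fell from 148 ± 29.3 to 53.5 ± 13.6 RPKM (-1.46 ± 0.31), and CSF1R (-0.55 ± 0.29) and CD14 (-0.17 ± 0.55) did not pass (0 and 1 adjusted over the list alone; camera, adjusted p = 0.382). Smoothing gave 1 higher and 0 lower in the tenocyte, 0 higher and 1 lower in the endothelial and 0 higher and 1 lower in the blood-cell list. Limma called 0 of 8 epithelial genes (camera, adjusted p = 0.518). KRT18 stood at 573 ± 213 RPKM in controls and 801 ± 415 in nSi libraries and KRT8, KRT7 and KRT14 had log2 fold changes of -0.83, 0.55 and 1.69. Limma also called 0 of 3 osteoclast genes (camera, adjusted p = 0.480), with SIGLEC15 (-0.55 ± 0.39), NFATC1 (-0.31 ± 0.40) and CTSK (-0.45 ± 0.77).

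**Figure D3:**
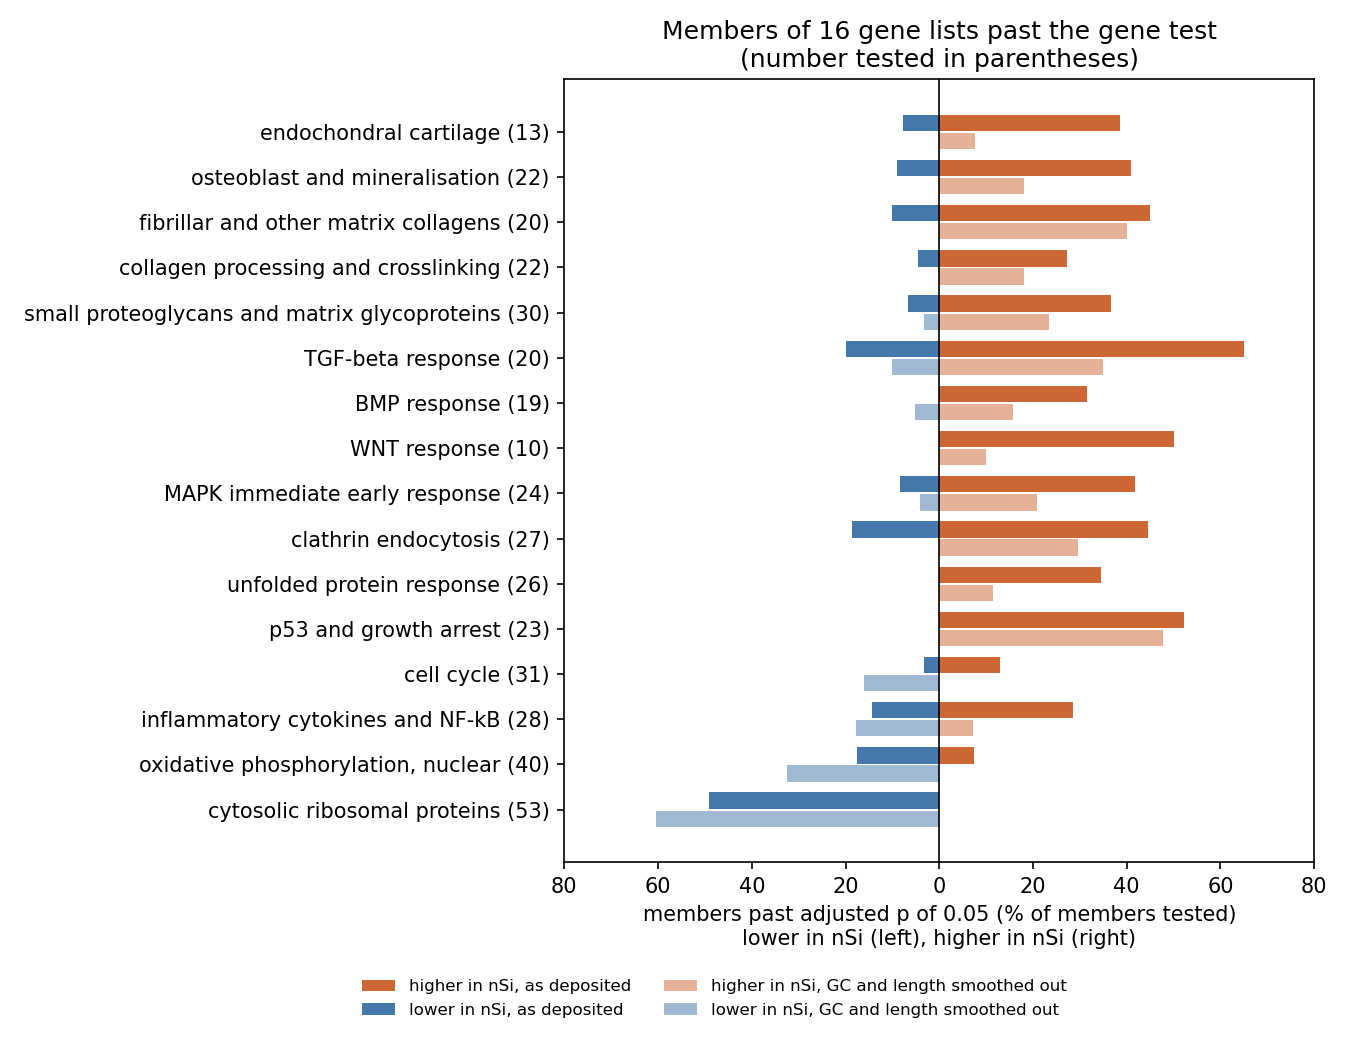
Share of the tested members of 16 gene lists (number tested in parentheses) past an adjusted p of 0.05, in % on the horizontal axis, to the right for members higher and to the left for members lower in nSi libraries, as deposited (dark bars) and with GC content and length smoothed out (light bars). Ribosomal protein genes have bars to the left only, 26 and 32 of 53 genes, and p53 and growth-arrest genes to the right only, 12 and 11 of 23. Cell cycle bars go from 4 higher and 1 lower to 0 higher and 5 lower of 31 genes.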

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

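The GC and length corrections and the voom fit were chosen after seeing the data. The counts of 4186 genes higher and 1252 lower moved by over 1.5 times as follows. Higher calls were 2427 with a filter at 5 RPKM, where fewer genes were tested, 2387 under quantile normalization, 1179 with the GC and length correction, 943 with the GC-by-level correction and 1873 with the replicate block and the GC correction together. Lower calls were 2687 under median-ratio scaling, 2475 under quantile normalization and 697 with the GC-by-level correction. Scaling moves lower calls by construction, since it shifts the median of all genes from 0.44 to near 0; for the rest the cause was not tested. With 1 library left out, which assumes that the lone library varies like the other group, higher calls ranged from 0 (without nSi replicate 2, 3927 at an unadjusted p under 0.05) to 3994 (without control replicate 2), and lower calls from 0 to 1275; without nSi replicate 1 they were 1471 and 13. Voom on recovered reads gave 4112 and 1333 calls, and 5155 of the 5438 calls as deposited were shared.

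The replicate block gave 4647 higher and 1476 lower calls. Deviations of libraries of one number correlated across genes at r = 0.35, but with 2 pairs, and no label that ties a number to a culture or day, the samples share only a number. The endochondral cartilage list stayed up without a call throughout (adjusted p 0.0571 to 0.970; 0.477 to 0.917 with 1 library left out). The osteoblast list turned down without control replicate 2 (adjusted p = 0.972; 0.522 to 0.972 over the left-out libraries), with no call on either side; the cause was not tested. With the GC-by-level correction 12 lists passed. The collagen processing list turned up there (adjusted p = 0.0161), and proteoglycans (0.0156), BMP (0.0396), endocytosis (0.0156) and the unfolded protein response (0.0156) were the other gains over the GC and length correction. None of the lists passed with an estimated correlation (adjusted p = 0.698 or more with an estimated correlation).

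Calls of genes named by rule that changed sign did so under a GC correction, which ended the call in each of these: with the GC and length correction MCM6 (-0.36), CCNA2 (-0.21), BIRC3 (-0.41) and APOE (0.024), with the same values under the block; with the GC-by-level correction MCM6 (-0.68), CCNA2 (-0.12), BIRC3 (-0.025), CBFB (-0.049), BMPR2 (-0.18) and WNT5A (-0.16). MKX (-0.83) and IBSP (-0.82), not called as deposited, were called lower with the block and the GC correction. Over 162 named genes, 2302 values across the alternatives kept direction and side of the threshold or changed sign with no call on either side (54 of them), 373 lost the call and 21 gained one. Over the other 33 lists the numbers were 589 (70), 6 and 29. At 11503198 to 12473233 reads, depth limits SP7, COL2A1 and COL10A1, which had at most 17 reads in a library.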

Other observations

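The tests of depth, smoothing, scaling, COMP reads and shared replicate numbers below were chosen after the results they measure were seen; the matched lists, the share of the most abundant genes and the 2 lists of the first paragraphs were set before their own values, but after the strongest changes, were seen. CTGF among the strongest rises led to a list of further targets of YAP and TEAD, the transcription regulators that respond to cell shape and adhesion. Of its 18 members not named in the report, which include the TEAD genes TEAD1 and TEAD4 themselves, 11 rose and 1, TEAD4 (-1.05), fell. CYR61, a matricellular relative of CTGF, went from 286 ± 72.0 to 1291 ± 67.3 RPKM (log2 fold change 2.19 ± 0.28), CRIM1 from 4.17 ± 0.310 to 72.1 ± 19.3 RPKM (3.80 ± 0.30), ASAP1 from 1.15 ± 0.163 to 16.2 ± 5.01 RPKM (2.97 ± 0.31) and LATS2, a kinase that restrains YAP, from 0.669 ± 0.118 to 9.11 ± 0.830 RPKM (2.60 ± 0.26), these 4 being picked out after their values were seen. With GC content and length smoothed out 7 were higher and 0 lower. The list then stood above other genes (camera, unadjusted p = 3.71e-05, and unadjusted p = 0.0467 with an estimated correlation). The values given for the 35 lists are adjusted, so the second p does not set this list apart from them. A hypothesis is that nanosilicate-exposed cultures may hold more YAP and TEAD activity after 21 days, which message levels in 2 libraries per group cannot settle; it was not tested further, and nuclear YAP protein with and without a YAP inhibitor would decide it.

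PSAT1 and SLC38A2 led in the same way to 25 further genes of the amino acid response, of which 1, ASNS, is also in the unfolded protein list. As deposited 11 rose and 1, AARS (-1.25), fell, with NARS going from 11.8 ± 4.19 to 155 ± 47.4 RPKM (log2 fold change 3.62 ± 0.37) and PSPH, the last enzyme of serine synthesis, from 8.30 ± 0.957 to 57.4 ± 7.26 RPKM (2.65 ± 0.27). With smoothing 2, NARS and PSPH, were higher and 1, AARS, lower. The list stood above other genes on the smoothed values (camera, unadjusted p = 0.00510, and unadjusted p = 0.475 with an estimated correlation). It did not as deposited (camera, unadjusted p = 0.113). A shared amino acid response may be present but rests on the preset correlation.

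AT-rich transcripts were higher and GC-rich ones lower in both nSi libraries, by -0.94 on the log2 scale per 10 percentage points of GC content, against 0.22 and 0.10 between replicates 1 and 2 of the control and nSi groups. Depth and a few dominant genes are argued against, since mean totals differed by 1.07 times and the 100 most abundant genes took 2.39 percentage points more of the reads in controls. A bias that follows transcript GC content and length smoothly is argued against as the whole cause of the calls. With both smoothed out, 24.6% of called genes with a GC value stayed past the threshold in the same direction. A library bias acting on other features of the messages would pass this smoothing, so the kept calls are not cleared of one. For the other 4090 called genes library preparation and a biological effect of nanosilicates cannot be told apart, because both controls stand on one side of the trend. The median absolute log2 fold change of these 4090 went from 1.39 (median standard error 0.29) to 0.46 (0.26). Smoothing left 3063 of them with a smaller fold of the same sign and changed the sign of 1007. The remaining 20, CXCL1, BDKRB1 and DKK3 included, had a fold as large or larger. The smallest adjusted p of any gene also went from 0.00249 to 0.0187. Genes that most cells use, picked out after their values were seen, were also low in both controls. CTNNB1 was at 6.03 and 5.82 RPKM against 128 and 111 in nSi, and YWHAZ at 10.8 and 24.7 RPKM against 284 and 375 in nSi. So were SEC23A (0.590 and 0.719 RPKM in controls), TCEA1 (1.31 and 1.25) and HIF1A (3.24 and 4.33), all among the 12 largest rises. A library step that loses AT-rich or long messages, such as one acting differently on RNA of different integrity, is a candidate explanation. It was not tested, and CTNNB1, at 47.4% GC content, lies near the median of 49.7% over tested genes.

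Of 53 ribosomal protein genes 26 fell, with a list call that ends at an estimated correlation (adjusted p = 0.970 with an estimated correlation). In these libraries GC content and length are argued against as the whole cause. The median of the ribosomal protein genes, -0.74, lay at percentile 0 of 10000 matched lists, whose medians ran from -0.54 to -0.20 in the central 95%. The matched genes were less abundant (median log2 level 10.31 against 11.45), so level stays open, and the draws take genes as independent. Scaling is argued against as the whole cause by quantile normalization only (camera, adjusted p = 0.0295; adjusted p = 0.956 with an estimated correlation; 12 members lower), since median-ratio scaling moves all genes about alike, and over all alternatives the adjusted p of the cytosolic ribosomal proteins list ran from 1.35e-18 to 0.970, the highest with an estimated correlation. For nuclear oxidative phosphorylation genes the median of -0.34 lay at percentile 7.09 of matched lists, inside their central range, while the GC-by-level correction left the list past the threshold (adjusted p = 0.00481; 1.92e-05 to 0.970 over the alternatives), so a shared fall and the make-up of these genes cannot be told apart; that this correction would also count was decided after the percentile, which alone would have fitted the make-up explanation, was seen. A hypothesis, not tested here, is that nanosilicate-exposed cells may invest less in ribosomes, which ribosome content or protein synthesis per cell would decide, and reads shared with pseudogenes stay open.

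Among panel genes COMP, ACAN, COL10A1, COL11A1 and IBSP were higher in replicate 1 than in replicate 2 of both groups, and SPP1, ALPL and SOX9 were lower. Counting noise is argued against for COMP, and was not tested for the others: COMP had 2467 and 34 reads in controls 1 and 2, a ratio per total of 70.7 with an exact 95% interval from 50.5 to 102. A culture, donor or day shared by libraries of one number may lie behind it, as replicate deviations correlated at 0.342 between the groups across genes with GC content and length smoothed out, but with 2 pairs this cannot be told apart from chance. No biological explanation was tested, since the labels name none for the number.

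Matched lists also placed other groups: the medians of the p53 and growth-arrest (1.37), TGF-beta (1.61) and collagen (0.93) lists lay at percentile 100 of 10000 lists matched on GC content, length and level, the osteoblast list (0.90) at 98.0 and the cell cycle list (-0.14) at 0.01. The endochondral median (1.32) lay at 99.6, but it is the fitted fold of MATN3, which had 0 reads in controls; with MATN3 at its bound the median was 1.14, just above the upper end (1.13) of the central 95% of its matched lists. These percentiles describe these libraries and are not tests of the groups.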
